A study of Mus musculus with 3 samples.

How the data were processed

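RNA was measured by sequencing in 3 libraries of mouse bone marrow cells, 1 library per group. Each library was a pool of sorted LSK cells, which lack the surface markers of mature blood lineages and carry Sca1 and c-Kit. Per the labels, the pools came from 10 wild-type mice aged 4 months, 5 Tif1g knockout mice aged 4 months and 5 wild-type mice aged 20 months, and 200000 LSK cells were sorted and pooled. The labels give the strain C57bl6x for every pool and call the wild-type mice littermates. Tif1g is the older name of Trim33. Groups were taken from the labels of each sample.

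The authors deposited a table of 39542 coding-sequence entries for each of the 3 pairs of libraries, in the column layout of Cuffdiff. Its levels are FPKM, fragments per kilobase scaled to the total of fragments, per the file headers. Its p-values and q-values are those of the authors' own test of each entry, per the file headers. TopHat and Cufflinks are named without versions, per the submitters' processing notes. The scaling method and the genome build are not given in the sources used here. The table pairs its entries with no gene symbols. Its loci on chromosome 7 reach 152.51 Mb, beyond the last annotated base of GRCm38 at 145.324 Mb, so its coordinates were not used. The authors also deposited a table of distinct 50-base read sequences with the count of each sequence in each library, per the file headers. Whether both mates of a read pair are in it is not given in the sources used here, so reads were treated as single reads.

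FPKM values of the authors' table were summed per gene over its coding-sequence entries, and 8094 genes with a mean of at least 1 over the 3 libraries and a usable status in every entry were kept. Differences were computed as log2 of the ratio of 2 libraries after adding 1. Genes at or beyond 2-fold were counted, and the same values gave the similarity of the comparisons. Entries of the authors' table at a q-value of 0.05 or under were counted as deposited.

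Because the authors' table has no symbols, Trim33, the named genes, the gene lists and the neighbours of Trim33 were measured from the deposited read counts, not from FPKM as first planned. Reads were matched on both strands to the basic transcripts of GENCODE M21 on GRCm38 through words of 25 bases that occur in a single gene. A read was given to a gene with at least 5 such words and no word specific to another gene, and genes with fewer than 100 such words were left out. Counts were divided by the number of gene-specific positions and scaled by median ratios over genes with at least 50 reads in each library, which gave RPKM, reads per kilobase scaled to library size. The scaling factors were 1.04, 1.12 and 0.859 for young wild type, knockout and old wild type. Reads matched the sense strand in 50.5%, 50.5% and 50.2% of cases, so overlapping and antisense genes cannot be separated, and members of near-identical families are uncertain where few of their positions are specific.

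Of the reads, 50725419, 52358723 and 49556264 matched 1 gene in young wild type, knockout and old wild type, or 64.9%, 63.4% and 65.8% of the total. A further 16.1%, 16.3% and 14.9% were shared between genes, and 16.6%, 17.8% and 16.6% held no transcript word. A level of 3 reads over 1 kilobase, the limit that a count of 0 allows, corresponds to 0.0591, 0.0573 and 0.0605 RPKM when scaled to the total of matched reads. On the median-ratio scale of the levels the limits differ somewhat, and the limit is highest in old wild type, which has the lowest factor. Ratios of levels carry no added value and have exact Clopper-Pearson 95% intervals from the read counts. Shares have Wilson 95% intervals. Reads are not independent molecules, so intervals and limits cover counting error only, not differences between mice.

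With 1 library per group there was no test between conditions. Gene lists were described by their median log2 difference, by the number of members at least 1.5-fold higher or lower, and by the percentile of the median among 10000 random lists of the same size, drawn within 20 bins of mean level. The genes named in each comparison are Trim33, the 12 highest and the 12 lowest by log2 difference among genes with a mean of at least 5 RPKM in both libraries, up to 4 members of each list with the largest absolute difference at a mean of at least 1 RPKM, and Tgfbr1, Slamf1, Selp and Vwf. Up to 10 genes per direction at least 2-fold different in both comparisons with young wild type were added. Predicted genes, immunoglobulin and T cell receptor segments, mitochondrial genes and the 5 genes of the sex-linked list, Xist and 4 Y-linked genes, were excluded from the ranking, while other genes of the X chromosome were kept. Immunoglobulin genes and Xist fall outside that rule and were chosen after their values were seen.

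For the similarity of the comparisons, which share the young wild-type library, 3 interchangeable libraries were simulated in 100 draws by handing the 3 values of each gene to the libraries at random, and counting error alone was simulated on the matched reads. Reads were also placed on transcripts with up to 3 mismatches to count bases that differ from the reference, at positions covered by at least 20 reads in every library. A base was called non-reference in a library at a share of at least 15% and absent at 2% or less. Windows of 5 Mb were marked from sites non-reference in at least 1 young library and absent in the old one, at least 8 in 3 genes. To test the windows on sites that did not mark them, genes were also divided at random into 2 sets, windows were marked from the sites of 1 set, at least 4 in 2 genes, and the sites of the other set were counted inside them, in 100 draws.

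Groups, comparisons, thresholds, the naming rule, 33 gene lists and most alternatives were fixed before the data were examined. The settings of read matching, median-ratio scaling of the reads, a list of plasma cell genes, the thresholds for non-reference bases and the window rule, which replaced a looser form with 5 sites in 2 genes and an earlier one of wider bins, were chosen after the data were seen. Alternatives to the pseudocount of 1 (0.1 and 5), the minimum level, the scaling, the fold threshold, the entries counted and the reads counted were tried.

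On simulated reads with 1% errors per base, 80.6% of 180000 reads were assigned, 99.95% of them to a simulated gene, and 0 of 20000 random sequences were assigned. On simulated counts for 11298 genes, 97.5% of 200 genes altered 4-fold passed the 2-fold rule and 0 unaltered genes did. Of 100 random lists, 4 fell outside percentiles 2.5 to 97.5. Of 50 planted base differences 43 were found, with 0 others. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.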

Results

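RNA was sequenced from pooled LSK cells of mouse bone marrow, the sorted fraction that holds hematopoietic stem cells and multipotent progenitors. The design had 3 groups with 1 library each, from 10 young wild-type mice (4 months), 5 young Tif1g knockout mice (4 months) and 5 old wild-type mice (20 months). Tif1g, now named Trim33, encodes a chromatin-associated ubiquitin ligase that acts on TGF-beta signalling. The libraries held 78200916 reads for young wild type, 82577406 for the knockout and 75347792 for old wild type, and 11275, 10988 and 11416 genes reached 1 RPKM. Immunoglobulin genes took 5.23% of matched reads in young wild type (Wilson 95% interval 5.22 to 5.24), 2.53% in the knockout (2.52 to 2.53) and 18.5% in old wild type (18.5 to 18.5). Xist, the X-inactivation transcript of female cells, had 11505 reads in young wild type, 45 in the knockout and 49 in old wild type, while the Y-linked gene Ddx3y was at 23.8, 28.8 and 26.5 RPKM, so the pools also differed in their content of Xist-expressing cells. No difference between libraries had a replicate check, and all intervals cover counting error only.

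Trim33 lies on chromosome 3 of GRCm38 from 103279293 to 103358775 and has 20 exons. Its level was 12.3 RPKM in young wild type, 7.35 RPKM in the knockout and 13 RPKM in old wild type. The ratio of knockout to young wild type was 0.599 (95% interval 0.575 to 0.625). Exons 2 to 4, at 103310309 to 103311513, held 268 reads in young wild type, 19 in the knockout and 213 in old wild type. Over these exons the ratio of knockout to young wild type was 0.0660 (0.0391 to 0.105), against 0.633 (0.603 to 0.665) over exon 1 and exons 5 to 20 together. Within the latter, exon 5, next to them, had a ratio of 0.307 (0.191 to 0.479). Reads joining exon 1 directly to exon 5 numbered 5 in the knockout and 0 in each wild-type library. Old wild type stood at 1.06 times young wild type for Trim33 (1.02 to 1.11), a log2 difference of 0.08 that became -0.14 when libraries were scaled to equal totals of matched reads.

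**Figure D1:**
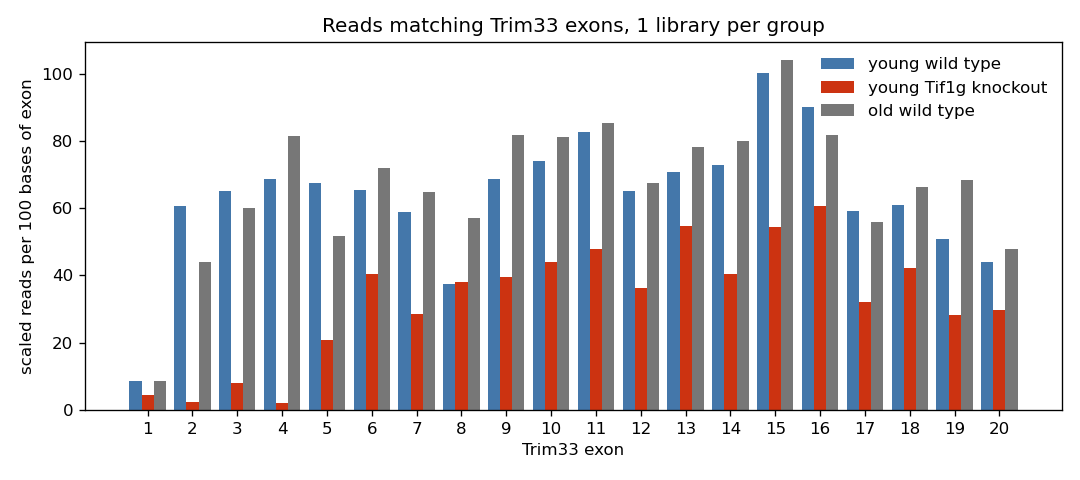
Scaled reads per 100 bases of each of the 20 Trim33 exons (bars, 1 library per group, no error bars). Exons 2 to 4 held 19 reads in the knockout library against 268 in young wild type and 213 in old wild type.

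The first comparison asked how young knockout LSK cells differed from young wild-type cells. Transcripts of differentiated blood cells, above all of macrophages, neutrophils, B cells and erythroid cells, were lower in the knockout library, while recombinase genes of early lymphoid cells and a cluster of stefin A genes were higher. The complement gene C1qb was 11.6-fold lower (10.2 to 13.2), at 4.22 against 48.9 RPKM, and the class II antigen-presentation gene H2-Aa was 7.99-fold lower (7.75 to 8.24), at 71.8 against 574 RPKM. Rag1, which encodes a subunit of the V(D)J recombinase, was 5.99-fold higher (5.43 to 6.62), at 8.12 against 1.35 RPKM. Of 8094 genes in the authors' FPKM, 225 differed at least 2-fold, 21 higher and 204 lower in the knockout. In the authors' deposited table, 262 of 21732 tested entries had a q-value of 0.05 or under, 25 higher and 237 lower.

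Among the macrophage genes, 12 of 13 measured members were at least 1.5-fold lower and 0 higher, with a median log2 difference of -2.06, at percentile 0 of the random lists. C1qa (9.93-fold lower), C1qc (10.5-fold lower) and Adgre1, the F4/80 antigen (10.4-fold lower), were among them. All 16 neutrophil granule genes were at least 1.5-fold lower (median -1.52), among them the antimicrobial peptide gene Camp at 4.09-fold (3.87 to 4.34) and the calprotectin subunit genes S100a8 at 3.59-fold and S100a9 at 3.64-fold. Of 15 B cell genes 10 were lower and 0 higher (median -1.13, or -0.60 with a pseudocount of 5), led by the class II genes H2-Eb1 at 9.16-fold and Cd74 at 7.07-fold, which antigen-presenting myeloid cells also express. Immunoglobulin transcripts moved the same way, with Ighm 4.79-fold lower (4.77 to 4.82) and Igkc 2.23-fold lower (2.22 to 2.24). Other transcripts among the 12 lowest were Cd209a, a lectin receptor of dendritic cells (15.6-fold), Ccr2, the chemokine receptor of inflammatory monocytes (9.87-fold), and the lectin genes Clec4a1 (13.5-fold) and Clec4a3 (12.4-fold). Ear2, Sirpb1a and Cd300ld3 were 12.8-fold, 18.5-fold and 16.0-fold lower, but 27.8%, 34.6% and 14.6% of their positions are specific to them and their levels are uncertain.

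Myeloid-priming genes were lower as a group beside these mature-cell transcripts: 16 of 24 members were at least 1.5-fold lower and 0 higher, with a median of -0.86 at percentile 0. Csf1r, the receptor of macrophage colony-stimulating factor, was 6.38-fold lower (6.06 to 6.71), Ms4a3 4.38-fold lower and the neutrophil elastase gene Elane 3.49-fold lower. Among these members only Nkg7 also stands in a list of mature cells, and without it the median was -0.86. Its removal could hardly move the median, so it does not show whether carried-over mature cells lower this list. Erythroid genes were lower in 14 of 18 members (median -0.93, or -0.43 with a pseudocount of 5), among them the blood-group gene Ermap at 3.51-fold and the water channel gene Aqp1 at 2.54-fold. Megakaryocyte and platelet genes were lower in 6 of 23 members (median -0.33), with Thbs1, thrombospondin 1, at 8.75-fold and Pf4, platelet factor 4, at 2.05-fold. Mast cell and basophil genes were lower in 5 of 11 members (median -0.25), with the basophil protease gene Mcpt8 at 2.56-fold.

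The lymphoid-priming genes had a median of 0.22 at percentile 100, with 8 of 28 members at least 1.5-fold higher and 2 lower. Besides Rag1, the recombinase gene Rag2 was 2.73-fold higher (2.45 to 3.03) and Il7r, the interleukin 7 receptor, 2.36-fold higher (2.16 to 2.58), while Ikzf3, a zinc finger factor of later lymphoid cells, was 3.23-fold lower. Vpreb1, a surrogate light chain gene, was 2.47-fold higher, with 42.6% of its positions specific. The highest differences were in the stefin A cysteine protease inhibitors on chromosome 16: Stfa1 (36276951 to 36285373) was at 44.3 RPKM in the knockout and 1.52 RPKM in young wild type, a ratio of 29.2 (20.2 to 43.9), and Stfa3, with 92.2% of its positions specific, was 28.9-fold higher (17 to 53.2). Stfa2, Stfa2l1 and BC100530 were 30.9-fold, 35.4-fold and 21-fold higher, and reads of these near-identical copies are uncertain between family members. Heat shock genes had a median of 0.22, with 4 of 18 members higher: Hsph1, an HSP110 chaperone, was 2.88-fold higher (2.78 to 2.98), and the inducible HSP70 genes Hspa1b and Hspa1a, which share most of their sequence, were 3.71-fold and 2.78-fold higher. Immediate early and dissociation stress genes were lower in 5 of 20 members and higher in 0 (median -0.29, percentile 0), with the transcription factor genes Klf4 6.35-fold and Nr4a1 3.93-fold lower. Fcgr2b, the inhibitory IgG receptor, was 2.46-fold higher (2.38 to 2.55). Zfp980, with 10.7% of its positions specific, was 2.94-fold higher, but its log2 difference of 1.34 became 0.15 when only fully matched reads were counted.

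TGF-beta receptors and signal transducers did not shift as a group: 3 of 24 members were lower and 0 higher, with a median of -0.02 that became 0.04 under equal totals. The endothelial receptor gene Acvrl1 was 4.33-fold lower (3.53 to 5.36), and the other lower members were Trim33 itself and Skil, an inhibitor of SMAD signalling (1.66-fold), while Tgfbr3 had a log2 difference of -0.50 with a ratio of 0.637 (0.584 to 0.694). Tgfbr1, the type I receptor, was at 10.6 RPKM in the knockout and 12.2 RPKM in young wild type, a ratio of 0.871 (0.833 to 0.911). Among TGF-beta response genes 5 of 16 were lower and 0 higher (median -0.14), led by Tgfbi, a matrix gene that macrophages also express, at 4.35-fold (4.10 to 4.62), and Id2, an inhibitor of DNA binding, at 2.55-fold.

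The second comparison asked how LSK cells of old wild-type mice differed from those of young ones. Genes known to be higher in aged stem cells, together with platelet, neutrophil, plasma cell and immediate early and dissociation stress genes, were higher in the old library, while interferon response and macrophage genes were lower. Aldh1a1, a retinaldehyde dehydrogenase, was 7.43-fold higher (6.85 to 8.07), Vwf, von Willebrand factor, 5.70-fold higher (5.31 to 6.13) and Slamf1, the stem cell marker CD150, 3.94-fold higher (3.38 to 4.61). In the authors' FPKM 184 of 8094 genes differed at least 2-fold, 138 higher and 46 lower in old wild type. The authors' deposited table had 179 of 22042 tested entries at a q-value of 0.05 or under, 148 higher and 31 lower. The old and young wild-type libraries also differed in immunoglobulin share and in base variants, given with the other observations, and scaling to equal totals moved the median of all genes by -0.22. Some named genes, among them Aldh1a1 and S100a8, start inside windows where the young libraries carried non-reference bases.

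Of the 24 measured genes known to be higher in aged stem cells, 18 were at least 1.5-fold higher and 0 lower, with a median of 1.10 at percentile 100. Selp, P-selectin, was at 14.1 against 8.02 RPKM, 1.75-fold higher (1.63 to 1.89), Cavin2, a caveolar coat gene, was 6.20-fold higher, and the metallothionein gene Mt1 was 5.23-fold higher (4.79 to 5.70). Mt2 was 9.77-fold higher, with 44.0% of its positions specific. Megakaryocyte and platelet genes, some of which are in both lists, were higher in 15 of 23 members and lower in 1 (median 0.94), with Pf4 4.64-fold higher (4.29 to 5.02) and the platelet glycoprotein gene Gp5 2.96-fold higher. Long-term stem cell markers were higher in 7 of 31 members and lower in 0, with a median of 0.19 that became -0.02 under equal totals; Mmrn1, multimerin 1, was 1.99-fold higher and Ly6a, which encodes Sca1, 1.80-fold higher. Multipotent progenitor markers were lower in 4 of 15 members and higher in 0 (median -0.41, percentile 0), among them Cd34 at 1.62-fold (1.60 to 1.64), the cytokine receptor gene Flt3 at 1.53-fold and Plac8 at 1.78-fold.

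Neutrophil granule genes were higher in 13 of 16 members and lower in 0 (median 1.54), with Retnlg 4.02-fold higher (3.61 to 4.49), Camp 3.21-fold higher and S100a8 3.12-fold higher. B cell genes were higher in 10 of 15 members (median 0.76), and all 16 plasma cell genes of the list written after the data were seen were higher (median 1.73). Derl3, a component of protein disposal in the endoplasmic reticulum, was 5.35-fold higher (5.06 to 5.66) and Prdm1, the plasma cell transcription factor BLIMP1, 4.22-fold higher; Mzb1 was 4.83-fold higher, with 23.0% of its positions specific. Ighm was 5.11-fold higher (5.10 to 5.13) and Jchain, the joining chain of secreted antibodies, was at 11456 against 3392 RPKM. Lymphoid-priming genes had a median of -0.02, with 5 of 28 members higher and 1 lower, and the members highest in old wild type included Jchain and Blnk, a B cell adaptor at 2.97-fold. Erythroid genes were higher in 8 of 18 members (median 0.40), with the carbonic anhydrase gene Car1 5.54-fold higher (5.29 to 5.79) and the erythroid transcription factor Klf1 3.29-fold higher. Under equal totals the medians became 0.19 for erythroid genes, -0.25 for lymphoid-priming genes and -0.52 for myeloid-priming genes.

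Immediate early and dissociation stress genes were higher in 11 of 20 members and lower in 1 (median 0.72), led by the AP-1 genes Fos at 6.87-fold (6.55 to 7.22), Fosb at 16.4-fold (13.2 to 20.6) and Jun at 4.39-fold (4.23 to 4.56). Jun and Junb, at 2.11-fold, were also the 2 members of the TGF-beta response list that were at least 1.5-fold higher; that list had a median of 0.13, which became -0.06 under equal totals. TGF-beta receptors and signal transducers had a median of -0.11 at percentile 0.29 with a mean of 0.01, and 2 of 24 were at least 1.5-fold higher, the BMP receptor gene Bmpr1a at 4.97-fold (4.21 to 5.89) and Tgfbr3 at 2.14-fold, while Tgfbr1 had a ratio of 0.863 (0.822 to 0.905). Interferon response genes were lower in 15 of 33 members and higher in 0 (median -0.49), with the antiviral genes Oas2 at 2.66-fold (2.49 to 2.85) and Ifi44 at 2.36-fold. Macrophage genes were lower in 9 of 13 members (median -0.77), and myeloid-priming genes were lower in 3 of 24 and higher in 1 (median -0.29), with Csf1r 2.38-fold lower (2.29 to 2.47) and Cebpe, a factor of granule formation, 2.5-fold higher. Slpi, a leukocyte protease inhibitor, was 8.31-fold higher (7.97 to 8.65), and Clca3a1 and Oosp1 were 5.96-fold and 5.32-fold higher. Ace, angiotensin-converting enzyme, was 4.33-fold lower (3.93 to 4.77), Hmga2, a chromatin protein of fetal stem cells, 4.13-fold lower (3.64 to 4.69), Fabp4, a fatty acid binding protein, 3.78-fold lower, Adgre4 3.66-fold lower, Myl10 3.50-fold lower and Treml4 3.26-fold lower. Zfp990, on chromosome 4 from 145510759 to 145539188, was at 0.753 RPKM in old and 34.5 RPKM in young wild type, with 42.0% of its positions specific, in a window where the young libraries carried non-reference bases; Oas1g, with 30.5% specific, was 3.98-fold lower.

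**Figure D2:**
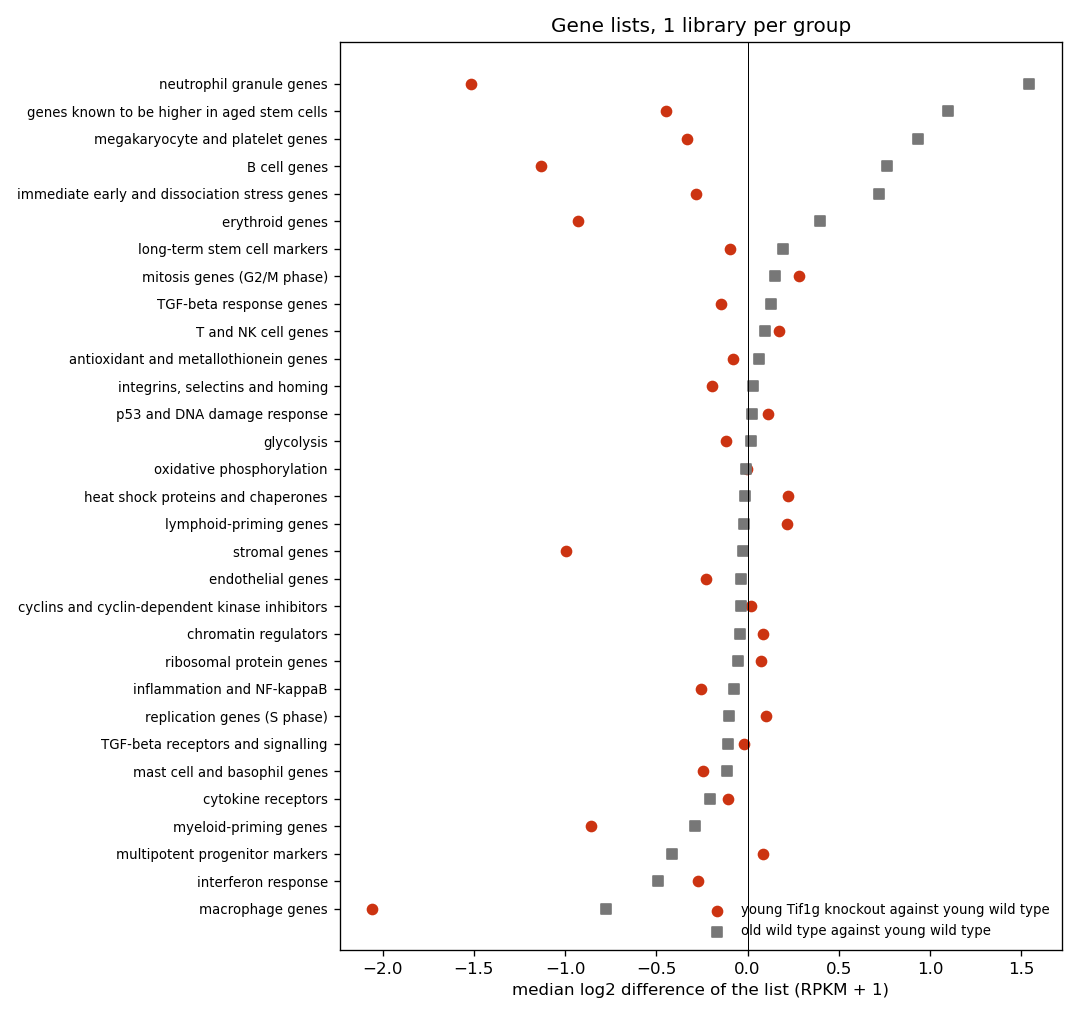
Median log2 difference (RPKM plus 1) of each gene list fixed before the data were examined, for the knockout (circles) and old wild type (squares) against young wild type, 1 library per group. The aged stem cell list lies at -0.45 in the knockout and 1.10 in old wild type, and the macrophage list at -2.06 and -0.77; medians near 0 can turn sign under equal totals of matched reads.

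The third comparison set old wild type against the young knockout. Genes of aged stem cells, platelets, erythroid cells, neutrophils and plasma cells were higher in old wild type, and the stefin A cluster and Hsph1 were lower. Vwf was 13.9-fold higher (12.6 to 15.4), Aldh1a1 13.2-fold higher (11.9 to 14.6), Slamf1 4.94-fold higher (4.20 to 5.84) and Selp 2.96-fold higher (2.72 to 3.23). In the authors' FPKM 394 of 8094 genes differed at least 2-fold, 344 higher and 50 lower in old wild type, and the authors' deposited table had 465 of 22003 tested entries at a q-value of 0.05 or under, 427 higher and 38 lower. Scaling to equal totals moved the median of all genes by -0.28.

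The aged stem cell list had 19 of 24 members higher and 1 lower (median 1.71), the megakaryocyte and platelet list 18 of 23 higher and 0 lower (median 1.25), and the long-term stem cell markers 10 of 31 higher and 1 lower (median 0.37). Multipotent progenitor markers were lower in 4 of 15 members (median -0.47), with Flt3 2.04-fold lower and Cd27, a costimulatory receptor, 1.77-fold lower. All 16 neutrophil granule genes were higher (median 3.03), with Camp 13.2-fold, Ngp 10.7-fold, S100a8 11.2-fold and Retnlg 12.7-fold higher, and all 16 plasma cell genes were higher (median 2.86), with the transcription factor gene Irf4 13.7-fold higher (12.7 to 14.7). Macrophage genes were higher in 11 of 13 members (median 1.33), B cell genes in 14 of 15 (median 2.19), erythroid genes in 14 of 18 (median 1.18) and myeloid-priming genes in 10 of 24 (median 0.54). Lymphoid-priming genes went both ways, with 4 of 28 higher and 10 lower (median -0.28); Rag1 was 5.73-fold lower in old wild type (5.16 to 6.37) and Ikzf3 10.9-fold higher. Immediate early and dissociation stress genes were higher in 17 of 20 members (median 1.09) and TGF-beta response genes in 7 of 16 (median 0.41). Under equal totals the medians became 0.11 for long-term stem cell markers, 0.25 for myeloid-priming genes and 0.21 for TGF-beta response genes. TGF-beta receptors had a median of -0.15 with a mean of 0.09, 5 of 24 being higher and 0 lower, and Tgfbr1 had a ratio of 0.990 (0.944 to 1.04), not distinguishable from 1 at this depth. Slpi was 20.1-fold higher (19.0 to 21.4), the sulfotransferase gene Chst1 27.2-fold higher (23.6 to 31.6) and Car1 12-fold higher. Stfa1 was 58.5-fold lower (33.3 to 114), Zfp990 94.6-fold lower (69.9 to 131), Fcgr2b 2.92-fold lower and Hsph1 2.84-fold lower. Fam102b, on chromosome 3 from 108970997 to 109027607 and thus within 20 Mb of Trim33, was 4.05-fold lower. The ubiquitin ligase gene Mid1 was 4.49-fold lower, and its log2 difference of -2.07 became -1.05 when only fully matched reads were counted.

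The title of the series raises an aging-like phenotype of knockout stem cells, so the differences of the knockout and of old wild type from young wild type were set side by side. Across the 8094 genes of the authors' FPKM, Pearson's r of the 2 sets of log2 differences was -0.03 and Spearman's rho -0.06; genes are not independent replicates and no p-value was computed. Both comparisons share the young wild-type library, which alone gives a positive correlation: 3 interchangeable libraries gave a mean r of 0.496 with a covariance of 0.0836, against an observed covariance of -0.0031. Counting error alone, simulated on the matched reads of 11298 genes, gave a covariance of 0.0021. The observed matched reads of those genes gave a covariance of 0.00059 and an r of 0.0047. In the FPKM, with the knockout or the old library as the shared reference, r was 0.766 or 0.661, which follows by arithmetic from the spreads and the covariance against young wild type. At the 2-fold threshold 1 gene was higher in both comparisons, 30 genes were lower in both and 29 went in opposite directions. The interchangeable libraries gave means of 48.9, 59.6 and 14.45 such genes, so the counts in the same direction lay below those means and the opposite count above. Independent lists of the same sizes, which leave out the shared library, would give 0.358, 1.16 and 3.60, and the difference from these is not read as a shared effect.

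The aged stem cell list went in opposite directions, with 0 members at least 1.5-fold higher and 11 of 24 lower in the knockout (median -0.45, percentile 0), against 18 higher in old wild type. The knockout median was -0.78 with a pseudocount of 0.1, -0.22 with 5, and -0.38 without members that stand in a list of mature cells. The members left out were the platelet genes Selp, Vwf, Cavin2 and Itgb3. The last value thus does not show whether carried-over mature cells lower this list. It stood beside lower medians of platelet genes (-0.33), myeloid-priming genes (-0.86) and macrophage genes (-2.06), so the lower values were not particular to aged stem cell genes. In the knockout Vwf was at 0.739 RPKM against 1.80 in young wild type (ratio 0.410, 0.364 to 0.461), Selp at 4.74 against 8.02 RPKM (0.591, 0.539 to 0.648) and Slamf1 at 1.22 against 1.53 RPKM (0.797, 0.652 to 0.975). Nupr1, a stress-response gene, and Gpr183, an oxysterol receptor, were 3.23-fold and 5.46-fold lower in the knockout. Long-term stem cell markers had a median of -0.09 in the knockout, with 3 of 31 lower and 0 higher, and multipotent progenitor markers a median of 0.08 with a mean of -0.06. By the read counts, among genes with a mean of at least 5 RPKM, 28 were at least 2-fold lower in both comparisons and 1 was higher. Among those lower in both, Adgre1 was at 17.3, 1.66 and 6.46 RPKM in young wild type, knockout and old wild type, the Fc receptor gene Fcgr4 at 19.0, 2.02 and 6.93 RPKM, and Slc11a1, a metal transporter of phagosomes, at 11.5, 1.18 and 4.23 RPKM. Ifi27l2a, an interferon-induced gene, was at 75.1, 21.7 and 30.9 RPKM, and interferon response genes as a list were lower in 7 of 33 members in the knockout (median -0.27). The gene higher in both was Cox6a2, a cytochrome c oxidase subunit, at 5.06, 12.7 and 13.1 RPKM.

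**Figure D3:**
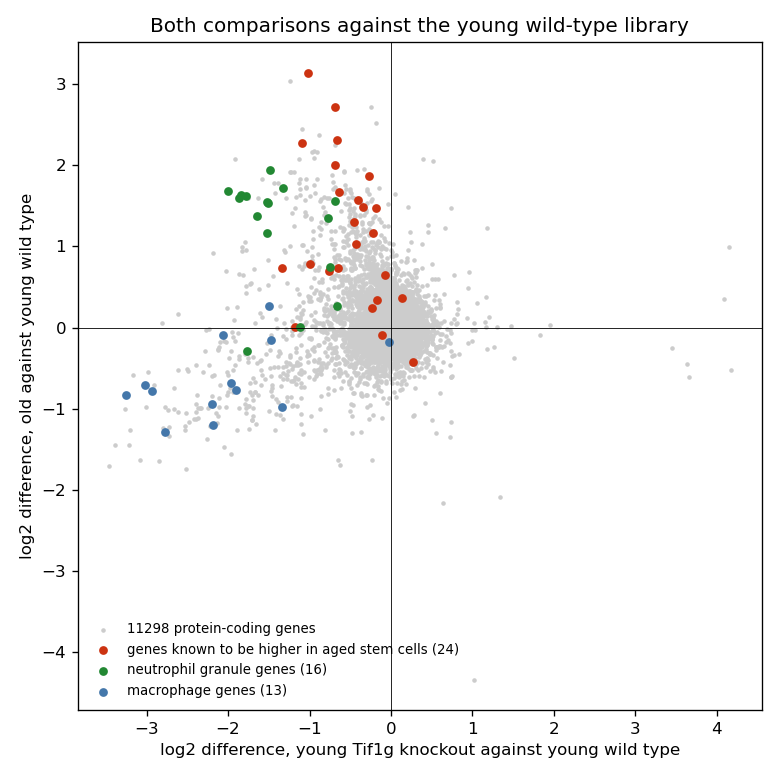
Each point is a protein-coding gene, with its log2 difference of the knockout (x axis) and of old wild type (y axis) against young wild type (RPKM plus 1, 1 library per group), and 3 gene lists in colour. The aged stem cell and neutrophil lists have medians of -0.45 and -1.52 on the x axis and 1.10 and 1.54 on the y axis, and the macrophage list lies at -2.06 and -0.77.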

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

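The tests of explanations here were chosen after the results were seen, and so was the list of plasma cell genes, while the scaling to equal totals and the other pseudocounts that they use were planned as alternatives.

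Bases that differ from the reference appeared in both young libraries and not in the old one at 1334 sites in 324 genes, a signal in read sequences that no comparison used. Among the 19132758 bases covered in every library, 273 sites were found in young wild type alone, 134 in the knockout alone, 145 in the old library alone and 2812 in all 3 libraries. In windows of 5 Mb marked from the sites of 1 random set of genes, the share of the other genes' sites was 7.79 times their share of covered bases (6.62 to 9.34 over 100 draws), against 1.01 (0.598 to 1.52) for the sites of the old library alone, which argues against errors that spread with the covered bases, though not against matching errors in clustered gene families. Genes at least 2-fold different between old and young wild type were no more frequent inside the 40 windows marked from all genes (2.45%) than outside (2.61%, upper bound 2.94), so alleles close to the genes that differ do not account for most of them. The young libraries also differed, with median non-reference shares of 33.5% in young wild type and 61.5% in the knockout over the 1334 sites. A wider set held sites that were non-reference in at least 1 young library and absent in the old one. Within 5 Mb of Trim33 that set had 51 sites in 15 genes, with medians of 9.38% in young wild type and 90.3% in the knockout. Medians of windows also use the wider set, so they are not directly comparable with those over the 1334 sites. On chromosome 1, the windows from 130 to 135 Mb and from 135 to 140 Mb had medians of 27.5% and 29.8% in young wild type. Both windows had a median of 0 in the knockout and in the old library. The labels give 1 strain, C57bl6x, for all libraries and call the wild-type mice littermates. Where these alleles came from, and their effects on genes elsewhere, stay open, since they go with age or genotype.

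Immunoglobulin genes took 5.23% of matched reads in young wild type, 2.53% in the knockout and 18.5% in old wild type, although a gate on lineage-negative cells is meant to remove antibody-producing cells. Transcripts of mature blood cells were lower in the knockout as a wider pattern. T and NK cell genes were not part of it, with a median of 0.17 and 1 of 10 members higher and 1 lower. A higher share of sorted progenitors alone would lower mature-cell transcripts alike only where progenitors do not express them. The medians of the macrophage and erythroid lists over all measured members differed by -1.13. Their middle ranges, -2.78 to -1.49 and -1.07 to -0.64, did not overlap with any of the 3 pseudocounts. The neutrophil and B cell ranges (-1.77 to -1.03, -2.16 to -0.50) overlapped that of macrophages with a pseudocount of 1. Levels in progenitors themselves were not measured, and erythroid genes expressed by progenitors would also drop less. The gap between the lists therefore cannot decide, and a higher share of progenitors stays open. Fewer plasma cells may account for the immunoglobulin part, which stays open: the median of the plasma cell list was -0.91 in the knockout against -0.77 for the 11 constant genes, and the larger gap, -0.41, was in old against young wild type, but the constant genes ranged from -2.80 (Ighg3) and -2.26 (Ighm) to -0.36 (Igha) and -0.10 (Ighd), with Jchain at 3392, 1764 and 11456 RPKM in young wild type, knockout and old wild type. Of the 16 plasma cell genes 3 are also in another list, others such as Xbp1 are expressed widely, and an effect of the genotype on the cells themselves remains open and was not tested. The knockout and young wild-type pools also differed in non-reference alleles and in Xist-expressing cells. Effects of these on the wider pattern stay open too.

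Genes known to be higher in aged stem cells were higher in the old library, with a median log2 difference of 1.10. Scaling to equal totals of matched reads moved the median of all genes by -0.22 and that of this list to 0.92. The choice between the 2 scalings is thus small beside the median of the list. Because that shift follows from the scaling itself, it is no separate test of the immunoglobulin reads. Alleles close to the members are argued against by the median of 1.03 outside the windows. Over members outside the megakaryocyte and platelet list the median was 0.91, so the genes shared by the lists, Selp, Vwf, Cavin2 and Itgb3, do not account for it. Levels of the other members in platelets and megakaryocytes were not measured, so carried-over cells of these kinds stay open. Age, named by the design, remains open as untested, and so do the genetic background and the presence of Xist-expressing cells in the young wild-type pool, since 1 pool stands for each group. The shares of stem cells and progenitors within each LSK pool were not measured, so a different mix of them stays open too. In this comparison multipotent progenitor markers had a median of -0.41 (-0.65 under equal totals). Long-term stem cell markers had a median of 0.19 (-0.02 under equal totals).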

How the results depend on the processing

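The tests that counted matched reads, fully matched reads, or genes and list members outside the windows or outside other lists were chosen after the data were seen; the others were planned. No paired analysis was possible because each group had 1 library, so no library could be left out either. Under the alternatives run, the direction of the count of 2-fold genes was kept in each comparison, with most genes lower in the knockout and most higher in old wild type. The counts, 225, 184 and 394 for knockout against young, old against young and old against knockout, became 97, 73 and 180 with a pseudocount of 5, 145, 113 and 241 with a minimum of 5 FPKM, and 116, 56 and 177 at a 3-fold threshold, as stricter rules must lower them. By matched reads they were 341, 293 and 597, over 11298 genes. In the authors' deposited table, 110 entries of old against young wild type had a q-value of 0.01 or under.

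The similarity of the comparisons was 0.77 with the knockout and 0.66 with the old library as the shared reference, where 3 interchangeable libraries gave a mean of 0.50. The 0.77 and 0.66 follow by arithmetic from the standard deviations (0.38 and 0.33) and the covariance (-0.0031) of the comparisons with young wild type, and so restate the value there. At the 3-fold threshold 0 genes were higher in both, 5 lower in both and 4 opposite. The Trim33 difference of -0.67 became -0.73 with a pseudocount of 0.1 and -0.48 with 5, and the share of its neighbours at least 1.5-fold different became 4.75% with no minimum level, as weakly expressed genes entered. The pseudocount also moved the aged stem cell list, to -0.78 (0.1) and -0.22 (5) in the knockout, to 0.62 (5) in old against young wild type, and to 2.32 (0.1) and 0.83 (5) in old against knockout.

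A reversal here is a change of sign of a list median that lay outside the central 95% of its random lists. Equal totals of matched reads moved TGF-beta receptors to -0.33 in old against young wild type and reversed TGF-beta response genes (-0.063), long-term stem cell markers (-0.020), mitosis genes (-0.068) and antioxidant genes (-0.18) there, and integrins (-0.040) and antioxidant genes (-0.11) in old against knockout; that scaling lowers every gene of the old library. Means in place of medians reversed TGF-beta receptors in old against young wild type (0.0069) and against the knockout (0.094), and multipotent progenitor markers (-0.064) and p53 genes (-0.0072) in the knockout. Medians inside the central 95% also differed in sign from their means: lymphoid-priming genes (mean 0.20), cyclins (0.057), heat shock genes (0.20) and oxidative phosphorylation genes (0.0022) in old against young wild type, and p53 genes (0.14), T and NK cell genes (0.19) and mast cell genes (0.23) in old against knockout. So did the universally used genes in all 3 comparisons (means -0.050, 0.000014 and 0.050). Such medians near 0 also changed sign under other settings. A minimum of 5 RPKM reversed TGF-beta response genes in old against young wild type (-0.089) and endothelial genes in the knockout (0.13), with fewer members measured. Beyond these construction effects the cause was not tested. For the other results, each combination of a result and a setting was counted. The value stayed within the interval of the main value in 1627 of these checks and moved beyond it in 732.

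The alternatives of the largest coding-sequence entry and of all statuses apply only to the authors' FPKM, so they gave no value for read-based results. Those of a minimum level gave no value for named genes other than Trim33, whose difference they leave as it is. Depth limits the lowest levels: 3 reads over 1 kilobase correspond to about 0.06 RPKM when scaled to the total of matched reads.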

Other observations

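Tests in this part were chosen after the results were seen, except those of the gene lists and of the neighbours of Trim33, which were planned.

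All 30 mitosis genes lay within 1.5-fold between the knockout and young wild-type libraries, with a median log2 difference of 0.28 at percentile 100, among them Cenpf, a kinetochore gene, at 1.47-fold (95% counting interval 1.41 to 1.52) and Kif23, a motor of cell division, at 1.36-fold; in old against young wild type the median was 0.15, which became -0.07 under equal totals. Replication genes, all 28 within 1.5-fold in both, had medians of 0.10 in the knockout and -0.10 in old wild type, with Ccne2, cyclin E2, 1.32-fold higher in the knockout (1.25 to 1.41). Cyclins and cyclin-dependent kinase inhibitors had medians of 0.02, at percentile 62.6, and -0.04 with no member beyond 1.5-fold, and p53 response genes of 0.11 (mean -0.01) and 0.02 (-0.19 under equal totals), although Trp53inp1 was 3.85-fold higher in old wild type (3.77 to 3.93) and Pmaip1, a BH3-only death gene, 3.81-fold lower in the knockout (3.19 to 4.57). Chromatin regulators had medians of 0.08 and -0.04, with Kmt2a 1.52-fold higher in the knockout and Cbx7, a Polycomb gene, 1.78-fold higher in old wild type. Oxidative phosphorylation genes lay at -0.00 and -0.01, glycolysis genes at -0.12 and 0.02 (-0.22 under equal totals), ribosomal protein genes at 0.07 and -0.05, and the 12 universally used genes at 0.01 and -0.05. Under equal totals, which moved the median of all genes by -0.22 in old against young wild type, the medians there became -0.33 for replication genes, -0.27 for cyclins, -0.28 for chromatin regulators, -0.25 for oxidative phosphorylation genes and -0.29 for ribosomal protein genes.

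Heat shock and chaperone genes had a median of -0.01 in old against young wild type, but the endoplasmic reticulum chaperones Pdia4 and Hsp90b1 were 2.41-fold and 2.15-fold higher (2.12 to 2.18 for Hsp90b1). Inflammation and NF-kappaB genes had medians of -0.26 in the knockout and -0.07 in old wild type, with Il1b, interleukin 1 beta, 16.0-fold lower in the knockout (11.6 to 22.8). Integrins and homing genes lay at -0.19 and 0.03 (-0.20 under equal totals), with Vcam1 5.86-fold lower in the knockout and Itgb3 2.75-fold higher in old wild type. Cytokine receptors lay at -0.11 and -0.21, and Epor, the erythropoietin receptor, was 2.76-fold lower in the knockout and 3.01-fold higher in old wild type. Antioxidant genes lay at -0.08 and 0.06 (-0.18 under equal totals), with Hmox1, heme oxygenase 1, 4.38-fold lower in the knockout. T and NK cell genes lay at 0.17 and 0.10 (-0.12 under equal totals), endothelial genes at -0.23 and -0.04, and mast cell genes at -0.11 in old wild type. Stromal genes lay at -0.99 and -0.02 over 6 measured members, with Cxcl12 3.90-fold lower in the knockout (3.62 to 4.21). Under equal totals the medians in old against young wild type became -0.24 for heat shock genes, -0.26 for inflammation genes, -0.43 for cytokine receptors, -0.34 for endothelial and mast cell genes and -0.22 for stromal genes. The 4 measured sex-linked genes, all on Y, had medians of 0.16 and 0.08. In all, 66 of 93 medians of lists lay outside the central 95% of their random lists, a count without a chance level here, since the members of a list are not independent and the 3 comparisons share libraries.

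Antibody classes differed in the old library. Ighg1 was 56.1-fold higher than in young wild type (48.7 to 65.0), Ighg2c 35.9-fold and Ighg2b 24.8-fold higher, against 2.72-fold for Igha. In the knockout Ighg3 was 7.75-fold lower than in young wild type (7.24 to 8.29) and Igha 1.28-fold lower. Growth of 1 B-lineage clone as the source of the old library's immunoglobulin reads was tested on kappa variable genes: the most used of 99 held 9.49% of their reads, where a dominant clone would hold over 50%, so that hypothesis is argued against.

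Within 20 Mb of Trim33, 20 of 267 genes (7.49%, Wilson 95% interval 4.90 to 11.3) differed at least 1.5-fold between knockout and young wild type, against 5.93% elsewhere, and 13 of 68 windows of 40 Mb had a share at least as high. The share was 5.62% (3.43 to 9.06) against 2.81% with a pseudocount of 5, 6.51% (3.92 to 10.6) against 3.95% at a minimum of 5 RPKM, and 6.34% against 5.96% within 10 Mb. In old against young wild type the share near Trim33 was 5.24%, against 6.43% elsewhere, and in old against knockout 14.6%, against 10.8%. The non-reference bases around Trim33, which also differed between these libraries, were not separated from other causes.

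Zfp990, on chromosome 4 inside a window of non-reference bases, was at 34.5, 71.2 and 0.753 RPKM in young wild type, knockout and old wild type. Its level was 2.06 times higher in the knockout than in young wild type, and the non-reference share in its window was 1.97 times higher. A candidate explanation is expression from the non-reference allele, but this is 1 gene chosen for its values, with 42.0% of its positions specific.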
